A study of Mus musculus with 6 samples.

How the data were processed

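Whole testes of mice labelled control (Lats1 and Lats2 floxed, 3 libraries) and knockout (the same alleles with Amh-cre, 3 libraries) were sequenced as RNA. Per the labels' protocols, frozen testes were thawed, total RNA was extracted with a Qiagen RNeasy kit, and reads were aligned with STAR. The submitters' processing notes name GRCm38 and the authors' use of DESeq2 1.22.2. The counting tool, the strand setting and the treatment of duplicate and multi-mapped reads are not given in the sources used here. The deposited table holds FPKM per library for 14998 genes, computed by the authors, together with the authors' p-values and FDR, −log10 p-values and log2 fold changes of mutant against control, and log2 group means per the file headers. In the file every gene reached 1 FPKM in at least 1 library, and the authors' group columns equal the log2 of the mean FPKM plus 0.01. The table lists no mitochondrially encoded gene. Column names of the table gave each library its group and number, with mutant read as knockout.

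FPKM values of a gene were whole multiples of the value of 1 read for 99.7% of genes (tolerance 0.003 reads), which gave whole reads and library totals. The absolute scale came from merged exon lengths in GENCODE M21, which the value of 1 read matched for 47.4% of genes with a length. Reads of 145 genes were multiplied by a whole factor from that length. The reads in the table came to 7087010, 9943591 and 9055847 for control and 9596210, 8686339 and 8941150 for knockout libraries. They were 73.0% to 74.8% of the totals that the FPKM imply in control and 77.9% to 78.9% in knockout libraries. Small differences between the groups therefore depend in part on the scaling. Replicate pairs differed by more than sampling noise in every case (mean chi-square per gene 1.70 to 5.03), so no pair was treated as 1 library deposited under 2 labels, which does not show that libraries came from separate animals. Gene IDs were matched to GENCODE M21, where 14842 were found, and coordinates are those of the deposited table, on GRCm38, counted from 1.

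Because FPKM are not counts, the planned count test was replaced by the test set beforehand for normalized values, limma 3.58.1 in R 4.3.3 with an intensity trend on log2(FPKM + 1), over genes with a mean of at least 1 FPKM, with Benjamini-Hochberg adjustment and a threshold of 0.05. All tests are two-sided. Adjusted p-values of genes come from this limma model and those of lists from limma's camera with a preset correlation of 0.01. Fold changes in FPKM are ratios of group means, and log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The 34 gene lists were fixed before the data were examined, from textbook knowledge, and 30 had the 5 measured members needed for a test. Of 634 list entries 536 matched the table, 10 of them by Ensembl ID where the symbol is an older one. The mitochondrial list had no member in the table. The list test was repeated with an estimated correlation, with ranks and with fry.

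Genes named in the text follow a rule fixed before the data were examined. It takes Lats1, Lats2, Yap1 and Wwtr1, the 8 largest rises and 8 largest falls among genes past the test with a mean of at least 10 FPKM and no overlap of the groups, for each list past its test the 3 members with the smallest p in its direction and 1 in the other, and for each other list the 2 members with the smallest p. Clone and predicted-gene names were left out of the largest rises and falls. Some genes that the rule takes are not reported here. Sox9, Klra4, Rpl4 and the members of the lists read later were chosen after their values were seen. On simulated data with 200 changed genes over 13719 tested, the test recovered 56% of genes changed 1.25-fold, 83.8% at 1.5-fold, 97.2% at 2-fold and 99.6% at 4-fold, with 4.97% of calls false. Alternatives were other pseudocounts and filters, leaving out each library, a replicate block, limma-voom on the recovered reads, stricter thresholds, median-ratio scaling and the removal of genes over a mean of 50 FPKM. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.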

Results

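RNA from whole mouse testes was sequenced in 6 libraries, 3 labelled control and 3 labelled knockout. Control animals carried Lats1 and Lats2 alleles flanked by loxP sites on both chromosomes, and knockout animals carried the same alleles with Amh-cre, a transgene that expresses Cre recombinase in Sertoli cells, the somatic cells that support germ cells inside the testis cords. LATS1 and LATS2 are the kinases of the Hippo pathway that restrain the transcriptional coactivators YAP and TAZ, and the comparison asks how testis expression differs when both are removed from Sertoli cells. The sample labels name testes, while the series' design text names adrenal glands, and the age of the animals is not stated in the labels. Values were the authors' FPKM (fragments per kilobase of exon, scaled to library size) for 14998 genes. The totals behind them, recovered from the size of single reads, were 9490735, 13620086 and 12104746 reads for control libraries 1 to 3 and 12322843, 11045693 and 11334996 reads for knockout libraries 1 to 3. A single read was worth a median of 0.0210 to 0.0301 FPKM. Nothing in the labels ties each library to a separate animal, so p-values measure the spread between these libraries, which may be technical in part. Replicates resembled each other more than the other group (Spearman correlation across genes 0.988 to 0.994 among controls and 0.994 to 0.996 among knockouts, against 0.866 to 0.889 between groups). Control replicate 3 stood apart from the other controls, at -15.8 on the second principal component (2.99% of the variance) against 7.85 and 8.26, and with a mean chi-square per gene of 3.97 and 5.03 to controls 1 and 2 against 1.90 between those.

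The targeted genes were examined first. Lats1 (chromosome 10, 7681209 to 7716458, GRCm38) had 15.7 ± 0.569 FPKM in control and 12.7 ± 0.239 FPKM in knockout libraries (SD, n = 3 each), a log2 fold change of -0.29 (SE 0.04, adjusted p = 0.000474). Lats2 (chromosome 14, 57642077 to 57758388) had 15.4, 14.5 and 17.0 FPKM in the control libraries and 17.8, 18.2 and 18.1 FPKM in the libraries labelled knockout. The rise of 0.20 on the log2 scale (SE 0.06, limma adjusted p = 0.0126) is opposite to the loss that the label names. Lats2 also belongs to the published YAP/TAZ target signature used below, from which it was left out as a deleted gene. The levels of Lats1 and Lats2 are over the whole gene in the whole organ, and the labels do not name the floxed exons. Amh-cre leaves both genes intact in other testis cells, and 42.4% of the annotated Lats2 exon bases are shared with the overlapping gene model Gm49361. Neither level therefore checks the deletion. For this reason the groups are called by their labels throughout, and each direction below is drawn from those labels. Yap1 (chromosome 9, 7931999 to 8004596), which encodes YAP, fell from 22.4 ± 0.658 to 18.5 ± 0.270 FPKM. Wwtr1 (chromosome 3, 57455649 to 57575910), which encodes TAZ, rose from 30.3 ± 0.875 to 58.3 ± 1.79 FPKM, 1.92-fold.

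Libraries labelled knockout differed from control libraries in 9492 of 13778 genes tested at an adjusted p of 0.05, with 4850 higher and 4642 lower, and 957 of the higher and 1107 of the lower genes moved by more than 2-fold on the log2(FPKM + 1) scale. Ankrd1 (chromosome 19, 36111965 to 36119844), an ankyrin repeat gene and YAP/TAZ target, rose from 1.49 ± 0.120 to 99.9 ± 5.92 FPKM, 66.9-fold. Ly6a, which encodes the surface antigen Sca-1, rose from 1.46 ± 0.233 to 85.1 ± 5.85 FPKM, and the cyclin-dependent kinase inhibitor genes Cdkn2b and Cdkn1a rose 45.3-fold and 33.8-fold, to 69.8 ± 2.06 and 51.5 ± 3.35 FPKM. Msln, which encodes mesothelin, reached 98.2 ± 7.15 FPKM from 4.30 ± 1.60 FPKM, the serine protease gene Prss23 reached 90.2 ± 5.47 from 4.42 ± 0.258 FPKM, and Scel, which encodes sciellin, reached 32.1 ± 1.06 from 0.876 ± 0.102 FPKM.

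Among the genes that fell, Amh (chromosome 10, 80805248 to 80807648), the gene of anti-Müllerian hormone, had 66.1 ± 2.71 FPKM in control and 1.03 ± 0.374 FPKM in knockout libraries, 64.2-fold less. Rhox8, a homeobox gene of Sertoli cells, went from 22.0 ± 8.07 to 0.239 ± 0.0273 FPKM, and Hsd17b1, a hydroxysteroid dehydrogenase gene, from 41.2 ± 5.03 to 1.88 ± 0.362 FPKM. Serpina5, which encodes a serine protease inhibitor, fell 30.7-fold from 41.7 ± 6.79 FPKM. Sel1l3 fell 22.1-fold, the adenosine receptor gene Adora1 20.3-fold, Spocd1, a gene of the germline piRNA pathway, 19.1-fold, and Kazald1 13.9-fold. Limma with Benjamini-Hochberg adjustment gave adjusted p-values from 8.91e-10 for Ankrd1 to 8.33e-07 for Rhox8 among the 8 rises and 8 falls. Over all genes tested, the values of the groups did not overlap in 74.3%, where chance gives 10% for 3 libraries against 3. The highest FPKM of any gene was 237.3, in the ribosomal protein gene Rpl4. Within a group, the shallowest library exceeded the deepest by more among the 51 genes with a mean of at least 100 FPKM than among genes at 10 to 50 FPKM (difference of median log2 ratios 0.10 in control and 0.04 in knockout libraries, bootstrap SE 0.01 each), so levels and folds of genes near that range, such as Ankrd1, Ctgf, Cyr61 and Hsd3b1, are less certain.

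**Figure D1:**
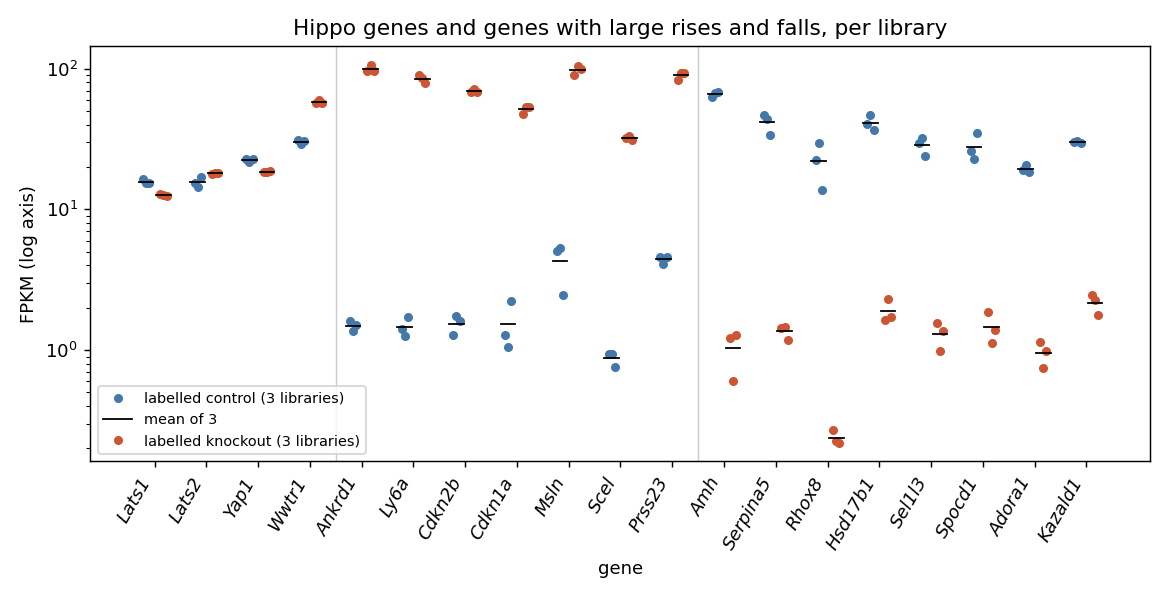
FPKM on a log axis for Lats1, Lats2, Yap1 and Wwtr1 and for the genes with large rises and falls that the text names. Points are single libraries (blue control, orange labelled knockout, 3 each) and black lines their means. Lats1 and Lats2 lie between 12.4 and 18.2 FPKM in every library, while Ankrd1 goes from a mean of 1.49 to 99.9 and Amh from 66.1 to 1.03.

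Genes of the Hippo pathway and its targets moved mostly upward. Of 21 measured YAP/TAZ target genes, 18 rose, 2 fell and 1 did not pass the test, with a median log2 fold change of 0.87 (camera adjusted p = 2.37e-06, and adjusted p = 0.255 with an estimated correlation). Macrophage genes in these libraries had a median of 2.91, Leydig cell genes -1.14, spermatogonial genes -1.69 and mesothelial genes, a list read later, 1.36. Besides Ankrd1, the matricellular genes Cyr61 (Ccn1) and Ctgf (Ccn2) rose 8.94-fold and 8.82-fold, to 147 ± 7.06 and 155 ± 6.31 FPKM. Nt5e, which encodes the ectonucleotidase CD73, fell from 23.2 ± 2.16 to 4.35 ± 0.390 FPKM. Among 25 pathway components other than Lats1 and Lats2, 17 rose, 5 fell and 3 did not pass (median 0.22, camera adjusted p = 0.0118, and adjusted p = 0.255 with an estimated correlation). Wwc1 and Wwc2, scaffold genes that act upstream of LATS, rose 8.08-fold and 3.10-fold, and Ptpn14, which encodes a phosphatase that holds YAP back, rose 3.32-fold. The atypical cadherin gene Fat4 fell from 7.93 ± 1.57 to 2.86 ± 0.248 FPKM. Over genes with a mean of at least 10 FPKM the component list did not pass (adjusted p = 0.0577).

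Sertoli cell identity genes fell as a list but not member by member. Of 32 measured, 24 fell, 6 rose and 2 did not pass (median -1.17, camera adjusted p = 1.31e-05, and adjusted p = 0.263 with an estimated correlation). Tesc, which encodes tescalcin, fell 9.88-fold from 23.3 ± 1.81 FPKM, and Mro, the maestro gene of the male gonad, fell 13.7-fold from 25.4 ± 2.68 FPKM, along with Amh. Fgf9, the growth factor gene that sustains Sox9 in the fetal testis, rose from 1.20 ± 0.185 to 6.67 ± 1.16 FPKM. In the same libraries spermatogonial and Leydig cell genes had medians of -1.69 and -1.14 and macrophage genes a median of 2.91. Junction genes of the blood-testis barrier went up in 10 of 16 cases and down in 4 (median 0.65, camera adjusted p = 0.0451, and adjusted p = 0.324 with an estimated correlation). Among them F11r, Cxadr and Pvrl2 (Nectin2), all genes of adhesion proteins of the immunoglobulin family, rose 1.95-fold, 2.54-fold and 1.85-fold, whereas the gap junction gene Gja1 fell from 95.6 ± 3.84 to 46.4 ± 1.69 FPKM. The junction list no longer passed without control replicate 3 (adjusted p = 0.0596), with no filter on low values (0.0658) or under median-ratio scaling (0.0559). Granulosa cell and ovarian genes did not pass as a list (3 higher, 5 lower and 4 not past of 12, adjusted p = 0.663, with fry and camera giving opposite directions). Within it Rspo1, an ovarian activator of WNT signalling, rose 4.21-fold to 31.0 ± 0.509 FPKM and the kinase gene Map3k15 fell 4.26-fold to 3.75 ± 0.573 FPKM.

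Germ cell genes were lower. In the list of prospermatogonia and spermatogonia 21 of 26 measured members fell, 1 rose and 4 did not pass (median -1.69, camera adjusted p = 7.12e-06, and adjusted p = 0.370 with an estimated correlation). Lin28a, an RNA-binding gene of undifferentiated germ cells, went from 8.24 ± 0.456 to 1.08 ± 0.401 FPKM, the DNA methylation cofactor gene Dnmt3l from 19.6 ± 4.63 to 2.33 ± 0.481 FPKM, and the piRNA pathway gene Tdrd9 from 33.3 ± 5.28 to 4.91 ± 1.53 FPKM. Etv5, a transcription factor gene that Sertoli cells express as well, rose 1.48-fold. Meiotic genes fell in 14 of 21 cases, 1 rose and 6 did not pass (median -1.05, camera adjusted p = 0.00334, and adjusted p = 0.590 with an estimated correlation). Rad51ap2, Spo11, which makes the meiotic double-strand breaks, and 4930528F23Rik (Meiob) fell 5.74-fold, 7.57-fold and 3.44-fold. Stra8, the gatekeeper gene of meiotic entry, was the member that rose, with 1.40, 2.36 and 0.963 FPKM in control and 18.8, 7.24 and 20.9 FPKM in knockout libraries (adjusted p = 0.000197). Of 6 measured spermatocyte and spermatid genes 5 fell and 1 did not pass (camera adjusted p = 0.0259, and adjusted p = 0.255 with an estimated correlation). Among them the lactate dehydrogenase gene Ldhc fell from 8.04 ± 1.78 to 0.700 ± 0.294 FPKM, and Piwil1 fell 7.32-fold. The transition protein gene Tnp1 fell 6.28-fold, a fold that depends on knockout replicate 2 (0.194, 1.08 and 0.211 FPKM in knockout replicates 1 to 3). The spermatocyte and spermatid list did not pass on recovered whole reads (camera adjusted p = 0.0784). Only 8 of its fixed members were among the deposited genes, and Prm1, Prm2, Tnp2 and Acr were not. Every deposited gene reached 1 FPKM in at least 1 library, so the missing members may have been low in control libraries too. The list therefore says little about late germ cells.

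Leydig cell and steroidogenic genes were lower in 15 of 17 cases and higher in 2 (median -1.14, camera adjusted p = 2.50e-05, and adjusted p = 0.255 with an estimated correlation). Hsd3b1, a steroid dehydrogenase gene needed for testosterone synthesis, fell from 144 ± 10.7 to 61.1 ± 3.84 FPKM, the renin gene Ren1 from 78.5 ± 11.1 to 16.5 ± 2.15 FPKM, and Fdxr, which passes electrons to mitochondrial steroid enzymes, from 34.8 ± 0.543 to 11.8 ± 0.485 FPKM. Vcam1, an adhesion gene that vessels also express, rose 3.49-fold. Interstitial fibroblast genes fell in 11 of 13 cases, with 1 higher and 1 not past (median -0.63, camera adjusted p = 0.00264, and adjusted p = 0.297 with an estimated correlation). The growth factor receptor gene Pdgfra and the transcription factor gene Gli1 fell 1.76-fold and 1.60-fold, and the collagen gene Col14a1 rose 2.44-fold. Peritubular myoid and smooth muscle genes did not pass as a list (6 higher, 4 lower and 3 not past of 13, adjusted p = 0.663, median 0.03 and mean -0.06), and its members Itga8, an integrin gene, and Tagln, which encodes transgelin, rose 2.78-fold and 2.10-fold. Endothelial genes, with 6 higher, 2 lower and 7 not past of 15, did not pass either (adjusted p = 0.129, and 0.0405 without knockout replicate 1). Flt1 and Emcn in that list rose 2.68-fold and 2.62-fold.

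Matrix and mesenchymal genes rose in part, in the same libraries in which macrophage genes had a median of 2.91 and interstitial fibroblast genes a median of -0.63. Extracellular matrix genes were higher in 22 of 36 cases, lower in 7 and not past in 7 (median 0.45, camera adjusted p = 0.00397, and adjusted p = 0.590 with an estimated correlation). Col8a1, a short-chain collagen gene, rose from 1.13 ± 0.119 to 34.5 ± 1.15 FPKM, and the basement membrane genes Lama5 and Nid2 rose 6.50-fold and 2.72-fold, while the elastin gene Eln fell from 28.9 ± 1.26 to 16.6 ± 1.03 FPKM. Of 20 mesenchymal transition genes 14 rose, 2 fell and 4 did not pass (median 0.64, camera adjusted p = 0.00438, and adjusted p = 0.324 with an estimated correlation). Tgfb1, Tgfbi, a matrix gene induced by TGF-beta, and the fibronectin receptor gene Itga5 rose 2.50-fold, 3.66-fold and 1.84-fold, and the transcription factor gene Snai2 fell 1.37-fold. TGF-beta and BMP response genes rose in 11 of 15 cases and fell in 3 (median 0.72, camera adjusted p = 0.00987, and adjusted p = 0.255 with an estimated correlation). In this list the BMP antagonist gene Nog, the ligand gene Bmp4 and Id3 rose 12.3-fold, 3.65-fold and 2.01-fold, and the list did not pass over genes with a mean of at least 10 FPKM (adjusted p = 0.113). Epithelial genes moved both ways (5 higher, 7 lower and 2 not past of 14, adjusted p = 0.469), with the keratin gene Krt19 4.22-fold higher and the protease inhibitor gene Spint2 1.87-fold lower.

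Macrophage genes were higher in all 19 measured cases (median 2.91, camera adjusted p = 5.65e-11, and adjusted p = 0.255 with an estimated correlation). The chemokine receptor gene Cx3cr1 rose from 5.06 ± 0.113 to 52.1 ± 3.41 FPKM, Ctss, a lysosomal protease gene, from 10.7 ± 0.450 to 87.1 ± 4.77 FPKM, and Csf1r, the receptor gene for macrophage colony-stimulating factor, from 4.08 ± 0.127 to 45.7 ± 3.09 FPKM. Inflammatory cytokine and NF-kB genes rose in 14 of 15 cases and 1 did not pass (median 1.77, camera adjusted p = 6.56e-07, and adjusted p = 0.187 with an estimated correlation). Csf1, the gene of the ligand of that receptor, rose 14.5-fold to 36.5 ± 1.83 FPKM, the prostaglandin synthase gene Ptgs2 14.3-fold to 9.70 ± 0.512 FPKM, and the chemokine gene Ccl2 from 0.165 ± 0.0846 to 6.90 ± 0.381 FPKM. Neutrophil genes did not pass as a list (1 higher and 7 not past of 8, adjusted p = 0.663), the higher member being Csf3r, 3.09-fold, and 7 erythroid genes had none past the test (adjusted p = 0.469, median 0.16). In the lymphocyte list, too small to test, 1 gene was higher and 2 lower. Interferon-stimulated genes did not pass as a list (8 higher, 3 lower and 7 not past of 18, adjusted p = 0.204), and its members Xaf1 and Oasl2 rose 4.47-fold and 3.73-fold.

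Stress and growth genes changed as well, beside the fall of germ cell genes and the rise of macrophage genes given above. Of 18 p53 target and apoptosis genes 15 rose and 3 did not pass (median 1.06, camera adjusted p = 2.13e-06, and adjusted p = 0.187 with an estimated correlation). Perp, a p53 effector gene, rose from 5.58 ± 0.449 to 56.3 ± 3.65 FPKM, and Ccng1 and the receptor gene Eda2r rose 3.32-fold and 7.96-fold. Proliferation genes fell by small amounts in 18 of 24 cases, with 1 higher and 5 not past (median -0.20, camera adjusted p = 0.00347, and adjusted p = 0.324 with an estimated correlation). The mitotic genes Bub1 and Kif11 and the replication gene Mcm6 fell 1.33-fold, 1.27-fold and 1.24-fold, and the cyclin gene Ccne1 rose 1.30-fold. Immediate early and heat shock genes, which also respond to the handling of tissue, rose in 12 of 15 cases and fell in 2 (median 0.78, camera adjusted p = 0.00172, and adjusted p = 0.255 with an estimated correlation). Ier3 rose from 5.46 ± 0.743 to 75.3 ± 1.05 FPKM, Dusp1 and Fos rose 6.85-fold and 14.7-fold, and the heat shock gene Hspa1a fell 2.14-fold. Cholesterol synthesis genes fell in 13 of 17 cases, with 1 higher and 3 not past (median -0.35, camera adjusted p = 0.00280, and adjusted p = 0.590 with an estimated correlation). Lss, Mvk and Mvd, enzyme genes of that pathway, fell 1.83-fold, 1.44-fold and 1.32-fold.

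Hedgehog, WNT and Notch response genes did not pass as a list (4 higher, 8 lower and 4 not past of 16, adjusted p = 0.204). Tcf7, a transcription factor gene of WNT signalling, fell from 45.0 ± 1.37 to 13.3 ± 1.23 FPKM, and the Notch target Hey2 rose 3.16-fold. Retinoic acid genes did not pass either (5 higher, 4 lower and 2 not past of 11, adjusted p = 0.663, median 0.03 and mean -0.12). Cyp26b1, the enzyme gene that breaks down retinoic acid in the fetal testis, fell from 20.5 ± 2.98 to 2.77 ± 0.245 FPKM.

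Lists for tissues that a dissected sample could carry were measured too. Skeletal muscle genes fell in 7 of 8 cases and 1 did not pass (median -1.19, camera adjusted p = 0.0136, adjusted p = 0.324 with an estimated correlation, and 0.0575 without control replicate 3), with Actn3 down from 8.48 ± 0.433 to 1.12 ± 0.480 FPKM, Myh2 from 1.92 ± 0.0259 to 0.0961 ± 0.0320 FPKM and Myh1 5.98-fold. Adrenal cortex and medulla genes, fixed because the design text names that gland, did not pass as a list (1 higher, 3 lower and 3 not past of 7, adjusted p = 0.328). Pnmt, the enzyme gene for adrenaline synthesis, had 19.3, 26.2 and 12.7 FPKM in control libraries and was listed at 0 in all 3 knockout libraries, and the corticotropin receptor gene Mc2r rose 2.35-fold. In lists too small to test, both rete testis and epididymis genes were lower, and of 3 adipocyte genes 2 were higher and 1 lower. Replication-dependent histone genes, whose RNA lacks a poly(A) tail, had 6 lower, 1 higher and 2 not past of 9 (adjusted p = 0.0816, and 0.00272 without control replicate 3), with Hist1h1e and Hist1h1b 2.87-fold and 3.37-fold lower.

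**Figure D2:**
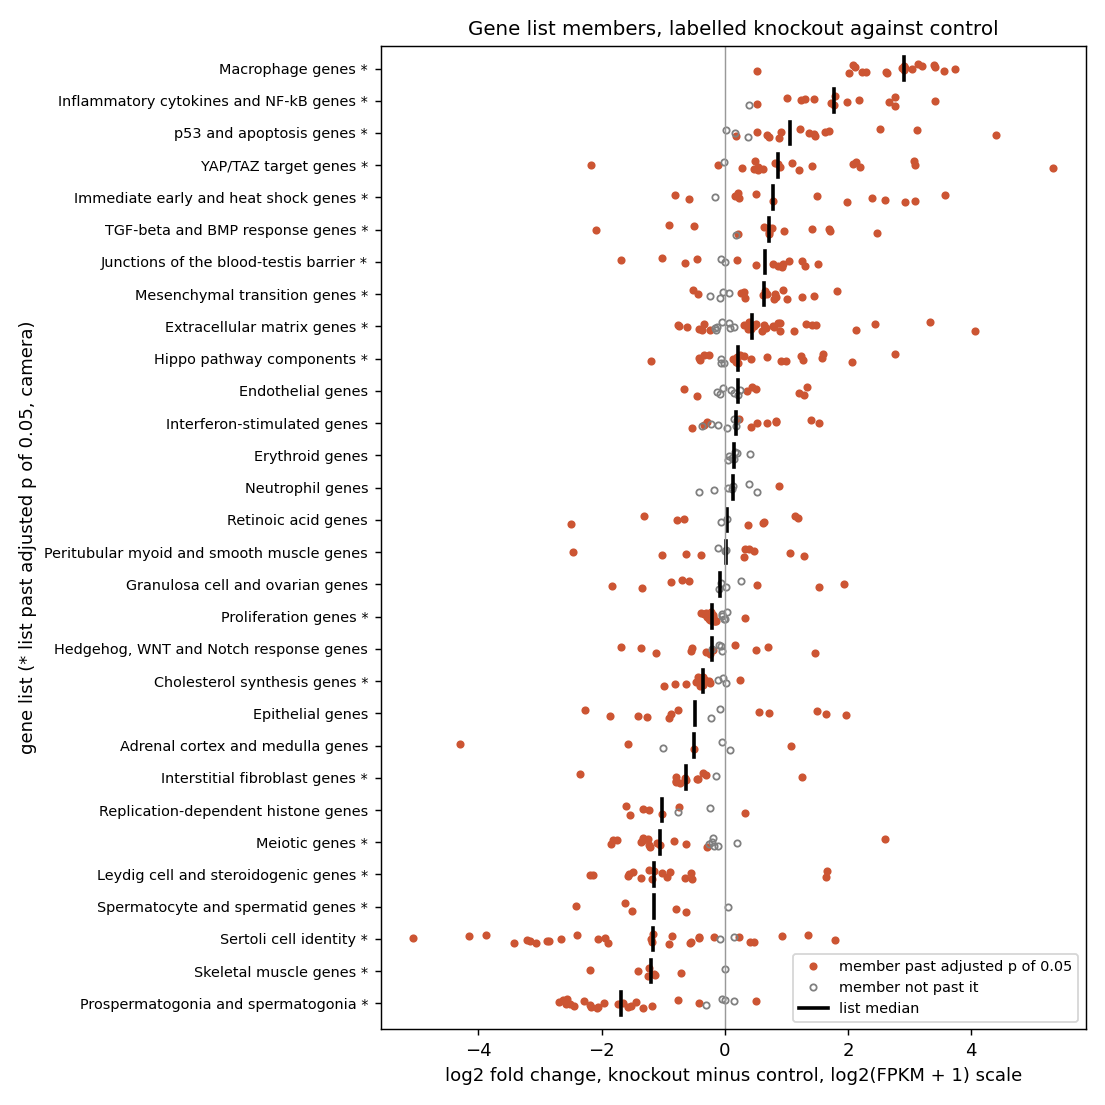
Log2 fold change (knockout minus control, log2(FPKM + 1) scale) of each measured member of the 30 gene lists tested, by list and sorted by the list median (black line). Filled orange points passed an adjusted p of 0.05, open grey points did not, and stars mark lists past an adjusted p of 0.05. All 19 macrophage genes lie to the right of 0, and Sertoli cell genes spread from -5.06 (Amh) to 1.79 (Fgf9).

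In all, 19 of 30 lists passed camera at an adjusted p of 0.05, and with an estimated correlation none of the 19 did, the lowest adjusted p being 0.187. Adjusted over the list alone, the member counts were as above except for p53 target genes (17 higher), TGF-beta and BMP response genes (12 higher), mesenchymal transition genes (3 lower) and peritubular myoid genes (5 lower). In the authors' deposited table the mutant was higher in 4688 genes and lower in 4384 at their FDR of 0.05. Of these, 8140 also passed the limma test, all 8140 in the same direction, and across genes their log2 fold changes and those fitted here had a Pearson correlation of 0.955, where genes are not independent replicates. The exons of Adora1, Csf1r, Ctgf, Hist1h1e, Hspa1a, Lats2, Map3k15, Prss23 and Tagln are shared by over 10% with another annotated gene. Hspa1a, Hsd3b1, Ren1, Ly6a, Myh1, Myh2 and the histone genes have close paralogs. The values of all these genes are less certain than those of the other genes that the naming rule takes.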

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

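The median-ratio scaling, the removal of genes over a mean FPKM of 50 and limma's treat in place of a count-based fold test were chosen after seeing the data, and all other alternatives were fixed before the data were examined. The main count was 9492 genes (4850 higher, 4642 lower). Over genes with a mean of at least 10 FPKM it was 4780 (2954 higher, 1826 lower) because 4716 of the main calls were not tested there, and against a 1.5-fold change it was 2546 (1266 higher, 1280 lower) because small changes no longer count. The count of gene lists was 19, and 0 with an estimated correlation, a setting that replaces the preset correlation and also tests on the few residual degrees of freedom. Camera with ranks, fry and every other setting in which lists were tested kept the count of lists within 1.5 times. Lists were not tested again at an adjusted p of 0.01 or against a 1.5-fold change. Pseudocounts of 0.1 and 5 gave 9456 and 9485 genes, no filter 10434, an adjusted p of 0.01 7872, median-ratio scaling 9601 (52.2% higher, against 51.1%), the removal of genes over 50 FPKM 9159, and limma-voom on recovered whole reads 9574 (41.9% higher). Leaving out each library in turn gave 8602 to 9412 genes. No gene called in the main test and in any of these was called in the other direction. The labels share replicate numbers without saying what they mark. The fit with a replicate block called 9359 genes, and deviations of same-numbered libraries correlated at -0.01, -0.02 and 0.10, so not every library matched its own number best and the numbers are not taken as pairs. With the block the histone list passed (adjusted p = 0.0463) and no other list changed sides. By fry, which compares no other genes, the interferon, endothelial, adrenal, Hedgehog, WNT and Notch, and retinoic acid lists passed as well. At an adjusted p of 0.01 Lats2 no longer passed, and against 1.5-fold 15 of the 108 genes that the naming rule takes did not. Settings fixed beforehand that need raw counts (other count normalizations, CPM filters and a second count model) were not run, as the file holds FPKM. In simulated data of the same depth, with 1 median spread for all genes and 200 changed genes, 56% of genes changed 1.25-fold were recovered. Of those changed 2-fold 97.2% were recovered, over 13719 genes. The real test called 9492 genes, so the adjustment left it a less strict p cutoff. The simulated shares therefore do not carry over to the real test.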

Other observations

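Gene groups outside the fixed lists were read after seeing the data. Motile cilia genes, which build beating cilia and sperm tails, fell in 15 of 16 measured cases (median -1.80, camera adjusted p = 1.19e-05, and adjusted p = 0.143 with an estimated correlation). Tekt1 went from 10.5 ± 2.57 to 0.621 ± 0.0678 FPKM and Ccdc113 from 17.6 ± 1.13 to 2.31 ± 0.714 FPKM (SD, n = 3). In the same libraries the spermatogonial, meiotic and spermatocyte and spermatid lists had medians of -1.69, -1.05 and -1.15. The exception was Foxj1, the master transcription factor gene of motile cilia, which rose from 0.356 ± 0.116 to 4.03 ± 0.397 FPKM. Mesothelial genes rose in 10 of 13 cases and fell in 3 (median 1.36, camera adjusted p = 0.00224, and adjusted p = 0.143 with an estimated correlation), with Upk1b 4.77-fold and Upk3b 2.71-fold higher, and 2 of the 13 are also in a fixed list.

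Mast cell genes rose in 7 of 9 cases, with 1 lower and 1 not past (median 1.34, camera adjusted p = 0.0147, and adjusted p = 0.447 with an estimated correlation). The mast cell protease genes Cpa3, Cma1, Tpsb2 and Tpsab1 rose 15.6-fold, 16.5-fold, 17.0-fold and 19.8-fold, Cpa3 to 27.3 ± 4.58 FPKM, while the amine transporter gene Slc18a2 fell 4.11-fold. MHC class II genes did not pass as a list (3 higher and 2 not past of 5, adjusted p = 0.131), with H2-Aa 7.80-fold higher and H2-Ab1 at 1.60 ± 0.431 and 2.23 ± 0.417 FPKM. Klra4, a receptor gene of natural killer cells, was listed at 0 in all 3 control libraries and had 7.37, 10.8 and 12.3 FPKM in knockout libraries. Including it, 8 genes were listed at 0 in every control library and above 0 in every knockout library, and 53 the other way round. Shared exons and close paralogs were not checked for genes read later, such as Klra4, Tpsb2 and Tpsab1. The treatment of multi-mapped reads is not given, so their levels may include reads of similar genes.

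The tests below were chosen after their own outcome was seen, except the list of retinoic acid induced genes and the exon overlap of Stra8. Those 2 were set before their own outcome was known, but after the rise of Stra8 was seen. For the fall of Sertoli cell genes, a lower share of Sertoli cells as the only cause would lower every member that no other cell type expresses. Of the 32 members 6 rose, among them Sox9, at a log2 fold change of 0.23 against -5.06 for Amh. Sox9 is the transcription factor gene that directs Sertoli cell fate. However, 4850 of all 13778 genes tested rose, and other testis cells express some of the members. The rise of these members could come from those cells, so the test cannot decide against a change in cell share alone. A candidate explanation that stays open is that the labelled genotype changes expression within Sertoli cells, alone or with a loss of some of them, which whole-organ RNA did not test.

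For the rise of macrophage genes, blood left in the tissue would raise erythroid genes as far. Against this, the mean log2 rise of the macrophage list exceeded that of the erythroid list by 2.55 (SE 0.18 over libraries). That SE leaves out the spread over the 7 erythroid genes, and the log2(FPKM + 1) scale understates the change of low genes. Fewer cells of the types whose genes fell would raise the markers of the remaining types alike, but the mean log2 rise of the macrophage list exceeded that of the endothelial list, 0.30, by 2.42 (SE 0.10 over libraries and 0.21 over members). Both tests argue against these as the source of the whole rise. The second takes endothelial cells to be retained, which was not tested. More macrophages in the libraries labelled knockout, or macrophages with higher expression, may each account for it, and the whole organ gives no test between them.

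For the rise of Stra8 beside the fall of Cyp26b1, more germ cells at every stage of meiosis would raise the other meiotic genes, but 14 of 20 fell and 0 rose (median log2 fold change -1.08), which argues against it, although the whole meiotic list had a camera adjusted p = 0.590 with an estimated correlation. A higher share of the remaining germ cells entering meiosis may account for it and stays open, since the median log2 ratio of mean FPKM of those 20 genes lay above that of the 26 spermatogonial genes by 0.77 (bootstrap SE 0.44), too little to decide. Reads of an overlapping gene are argued against by an exon overlap of 0% for Stra8 in the annotation. More retinoic acid signalling may contribute, but 8 measured genes known to be induced by retinoic acid had a median log2 fold change of 0.34. Of these, 5 were higher and 2 lower (limma's camera adjusted p = 0.431 over the lists read later). The 8 leave out the response genes of the fixed retinoic acid list. That list also holds synthesis and breakdown genes, so it does not test the response genes alone. With 5 members higher and 4 lower, it did not pass camera (adjusted p = 0.663) but passed fry upward (adjusted p = 0.00177). More signalling therefore cannot be told apart from no change in that signal. An effect of the labelled genotype by way of Sertoli cells stays open and was not tested.

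For the count of called genes, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many as 9492 genes, and the highest of the others gave 0. With 10 splits the share cannot fall under 0.05, so the splits alone do not settle whether chance is excluded.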
